A study of Mus musculus with 12 samples.

How the data were processed

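Poly(A) RNA was measured by RNA-seq in 12 libraries from mouse small intestine. Per the labels, crypts, villi and cultured organoids were taken from duodenum, jejunum and ileum, which gives 9 groups of tissue and origin. Each crypt group has 2 libraries, and each organoid and villus group has 1, so organoid and villus groups have no replicates. The organoids had been in culture for 12 weeks per the labels. The labels do not say that replicates come from separate animals, so every p-value measures only the spread between these samples. RNA was prepared with Trizol LS and selected with Poly(A)Purist MAG and an mRNA-ONLY kit, and libraries were made with the SOLiD Total RNA-Seq Kit and read as 50-bp reads on a SOLiD 4, per the labels' protocols. Reads were aligned with BWA to the mouse build mm9, per the submitters' processing notes. The versions, the gene models and the rule for counting reads, including any use of strand, are not given in the sources used here.

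The deposited values are RPKM, reads per kilobase of exon scaled to the reads of the library, 1 value per transcript and library, per the file headers. The plan written before the data were examined assumed read counts. Because the unit was RPKM, the test planned for normalised values was used instead, which is limma with a mean-variance trend on log2(RPKM + 1). Fold changes are on that scale and understate the change of genes with low RPKM. The tables hold 21247 transcripts with 19012 symbols, of which 1520 have several transcripts (56 of these at several loci), and the transcript with the longest exons was kept for each symbol. The reference table gave a current symbol for 18507 of the symbols through its RefSeq accession. Symbols are printed as deposited, with the current symbol beside an older one at first mention. Coordinates are those of mm9, and whether the first base is counted from 0 or 1 is not given in the sources used here.

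RPKM values were multiples of the value of 1 read, so read numbers could be recovered. At least 99.9535% of the values in each library came out as whole reads within 0.02 of a read. The implied totals lay between 5268480 and 18591819 reads, and the reads in annotated genes between 2332849 and 10935217. At these depths 1 read in a 2-kb gene is worth between 0.0269 and 0.0949 RPKM. A gene was tested when it had the equivalent of 10 reads at median depth in at least 2 libraries for the crypt comparisons, 3 libraries for the tissue comparisons and 1 library for the differences between tissues in the ileum-duodenum difference, with at least 15 reads in total. This left 11123, 11825 and 12740 genes. Reads shared between near-identical paralogs, as among the defensins, cannot be assigned with certainty, and neither can reads from overlapping or antisense genes. Among expressed symbols, 6 share all their values with another one, Defcr24 with Defcr6 among them.

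The crypt comparisons between origins used the 6 crypt libraries with 1 mean per origin, which leaves 3 residual degrees of freedom. Tissues were compared over all 12 libraries in an additive model of tissue and origin with 7 residual degrees of freedom, and the same model gave the ileum-duodenum difference across tissues. Villi and organoids have 1 library per origin, so the 3 origins served as the replicates of these tissues. A preparation shared by the libraries of a tissue cannot be told apart from the tissue in this model. Whether the ileum-duodenum difference of organoids or villi differs from that of crypts was tested in a model with 9 means, in which the single libraries are assumed to vary like the crypt libraries. All p-values of genes are two-sided, come from limma and were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. The 34 gene lists, with 409 of their 418 entries matched, were fixed before the data were examined. A list was tested with limma's camera at the preset correlation, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals and with fry. Lists with fewer than 3 tested members were not tested. Counts of members are given over all genes and adjusted over the list alone.

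Genes named in the text follow a rule fixed before the data were examined. It takes the 8 largest changes per direction for crypt ileum against crypt duodenum and the 5 largest for other comparisons, among genes past the threshold with an average log2 CPM of at least 3 and libraries that do not overlap or the same direction at all 3 origins. It adds the 2 to 4 list members with the smallest p-values, or up to 2 abundant members where none passed, 20 genes named in any case, and 5 genes per direction that keep or lose the crypt difference in organoids. Some of those genes had no match and are not named. Genes named outside the rule are marked as chosen after their values were seen.

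The labels number the crypt replicates 1 and 2 at each origin, so it was checked whether equal numbers deviate together. The deviations from the group means correlated across genes at 0.421, 0.508 and 0.792 for the 3 pairs of origins, and at 0.408, 0.485 and 0.794 with median-ratio scaling. The numbers therefore pair the crypt libraries, which was decided before the calls of the fits were compared. The planned design had no block. For villus or organoid against crypt the block was added after the data were seen, as the replicate difference centred within crypts. The value from the fit with the replicate number as a block stands beside a result where it changes a call or moves a count by more than 1.5 times.

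The fits were tested, after the real results had been seen, on simulated data with 200 changed genes, a residual SD of 0.29 and a replicate effect with an SD of 0.698, both in log2 units. The replicate effect of a gene was the same at each origin, as the blocked fit assumes. In the real data the deviations of duodenal crypts correlated with those of jejunal and ileal crypts at only 0.421 and 0.508. Recovery and false calls of the blocked crypt fit are therefore those of a favourable case. For crypt ileum against crypt duodenum, over 11132 genes, the fit without the block recovered 0%, 0% and 13.3% of changes of 2-fold, 4-fold and 8-fold, with 0 false calls, and the blocked fit recovered 35.2%, 98.6% and 100% with 9 false calls. For villus against crypt, over 11550 genes, 23.1%, 95.6% and 98.1% were recovered. For organoid against crypt, over 11564 genes, the shares were 27.7%, 95.3% and 98.6%. False calls numbered 0 and 1 in these 2 comparisons without the block, and 1429 and 1370 with it. The simulated villus and organoid libraries varied independently, with no effect shared by the libraries of a tissue and no origin difference. These counts therefore do not cover false calls from a shared preparation. For the ileum-duodenum difference of organoids against that of crypts, over 11963 genes, no change was recovered without the block, and 0%, 30.1% and 76.7% with it. In the simulated list test camera called the shifted list of 20 genes and 0 of the other lists, of 34 in all. That test had no replicate effect and drew each gene independently. It therefore cannot show how many false list calls camera makes where the members of a list move together.

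Shares of crypt genes that keep their direction in organoids or villi have 95% Wilson intervals, which treat genes as independent and cover counting error only. They were set beside 10000 random lists of the same size matched on mean expression in 20 bins. A gene counted as kept when its log2 ratio of ileum to duodenum was at least 1 in the same direction. The alternatives were other pseudocounts and filters, the replicate block, other libraries in the fit, leaving out each library in turn, removal of the 20 most abundant genes, and, chosen after seeing the data, median-ratio scaling, limma-voom on the recovered reads, another transcript per symbol, leaving out all crypt libraries of 1 replicate number, and testing the same genes when 1 crypt library is left out. R 4.3.3 with limma 3.58.1 was used for the tests, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for tables and plots.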

Results

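Poly(A) RNA was measured in epithelium of the mouse small intestine at 3 origins along its length, duodenum, jejunum and ileum, and in 3 tissues. Crypts hold the stem and Paneth cells and villi hold the mature enterocytes. Organoids are epithelial cultures grown from crypts, here sampled after 12 weeks. There were 2 crypt libraries and 1 organoid and 1 villus library per origin, 12 in all. The implied totals were 5268480, 8721535 and 8945045 reads in crypt replicate 1 and 9426733, 9253502 and 10275855 reads in crypt replicate 2 of duodenum, jejunum and ileum. Organoids had 10829828, 18591819 and 13781355 reads and villi 13094383, 12804038 and 12118586. The share of these reads in annotated genes was 44.3% to 52.3% in crypt replicate 1, 60.1% to 67.6% in crypt replicate 2, 58.8% to 75.0% in organoids and 67.8% to 75.8% in villi. The question the design addresses is whether the location of the tissue of origin stays recorded in epithelial stem cells once they are taken out of the body.

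Genes of mature enterocytes separated the crypt replicates at every origin. Of 17 enterocyte genes, 16 in duodenum, 17 in jejunum and 17 in ileum were higher in replicate 2, by a median log2 difference of 2.95, 2.98 and 2.92. Fabp1, which carries fatty acids in enterocytes, was at 72.9 and 1130 RPKM in the 2 duodenal crypt libraries, and Cyp3a11, a drug-metabolising cytochrome, was listed at 0 and at 43.7 RPKM. The Paneth cell genes were lower in replicate 2, by medians of -1.82, -0.83 and -1.37 for duodenum, jejunum and ileum, and so were the MHC class II genes, by -1.26, -2.83 and -1.99. Genes of these groups therefore carry a spread between replicates. The fit with the replicate block removes only the part shared by the 3 origins, and the Paneth and MHC class II medians differ between origins.

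Ileal and duodenal crypts differed most clearly in transcription factors that mark position along the body axis. Hoxb9, Hoxb8 and Hoxb6, homeodomain factors of a single cluster, rose in ileal crypts, and Onecut2, a homeodomain factor of foregut derivatives, fell. These were the 4 genes past the threshold, 3 higher in ileum and 1 higher in duodenum, while 455 of 11123 genes had an unadjusted p under 0.05. With the replicate block 37 genes passed, 25 higher in ileum and 12 higher in duodenum, all 4 genes among them. The blocked genes add Gata4, a zinc finger factor, Fabp1 and the apolipoprotein Apoa4 on the duodenal side, and the bile acid-binding protein Fabp6 and Paneth cell defensins on the ileal side. Leaving out 1 duodenal or jejunal crypt library left 0 genes. Without an ileal one Hoxb9 and Hoxb8 no longer reached the 2 libraries asked for and were not tested, Hoxb6 and Onecut2 did not pass, and 1 other gene passed without ileum replicate 1. With the same 11123 genes tested, a choice made after seeing the data, Hoxb9 passed without either ileal library (adjusted p = 0.00773 and 0.0431 without replicate 1 and 2). Hoxb8 and Hoxb6 then passed without replicate 1 (0.0273 for both) and not without replicate 2 (0.0592 for both), and Onecut2 in neither case (0.0592 and 0.123).

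Hoxb9 (chromosome 11, 96132643 to 96137906, forward strand) rose by a log2 fold change of 4.47 (SE 0.31, limma adjusted p = 0.0227). Its RPKM was 0.129 ± 0.0161 (SD, n = 2) in duodenal, 0.149 ± 0.21 in jejunal and 24.2 ± 4.74 in ileal crypts. Hoxb6 (chromosome 11, 96160484 to 96162882) rose by 3.96 (SE 0.32, limma adjusted p = 0.0227), from 0.336 ± 0.134 to 19.8 ± 2.74 RPKM (SD, n = 2). Hoxb8 (chromosome 11, 96143218 to 96146638) rose by 2.83 (SE 0.24, limma adjusted p = 0.0227) and reached 6.64 ± 1.02 RPKM (SD, n = 2) in ileum. Onecut2 (chromosome 18, 64500017 to 64558141) fell by 4.57 (SE 0.38, limma adjusted p = 0.0227), from 25.3 ± 7.12 RPKM in duodenal and 6.48 ± 1.37 in jejunal crypts to 0.0881 ± 0.0526 in ileal crypts (SD, n = 2). Each of these differences exceeded the spread between replicates. Gata4 (chromosome 14, 63817751 to 63864096, reverse strand) had a log2 fold change of -3.07 with an adjusted p of 0.543, and of 0.0106 with the block, where its SE went from 0.72 to 0.26. Osr2, a zinc finger factor, was higher in ileum by 2.77 with an adjusted p of 0.385, and of 0.0326 with the block.

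The tested members of the Hox list were higher in ileal crypts as a group. Of the 39 matched Hox genes, those tested had enough reads in 2 crypt libraries, which Hoxb9 and Hoxb8 reached only through the ileal ones. This favours members high at 1 origin, so the values describe the tested members and not the whole list. Of the 11 tested members 3 rose over all genes and 9 did adjusted over the list alone (7 and 10 with the block), and the median log2 fold change was 2.83. Over the 16 Hox genes that passed the wider filter of 1 library the median ratio was 0.74, with 13 higher in ileum and 7 at a ratio of at least 1. Hoxb5, Hoxb4 and Hoxb7 were the next members, with adjusted p-values of 0.0162, 0.0162 and 0.028 with the block. The camera adjusted p was 1.57e-34, and the call held with an estimated correlation (adjusted p = 0.0397), the only one of 13 called lists to do so. With the block it was lost under the estimated correlation (adjusted p = 0.326). Of the proximal transcription factors only Onecut2 and Gata4 could be tested, and both fell adjusted over the list alone.

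**Figure D1:**
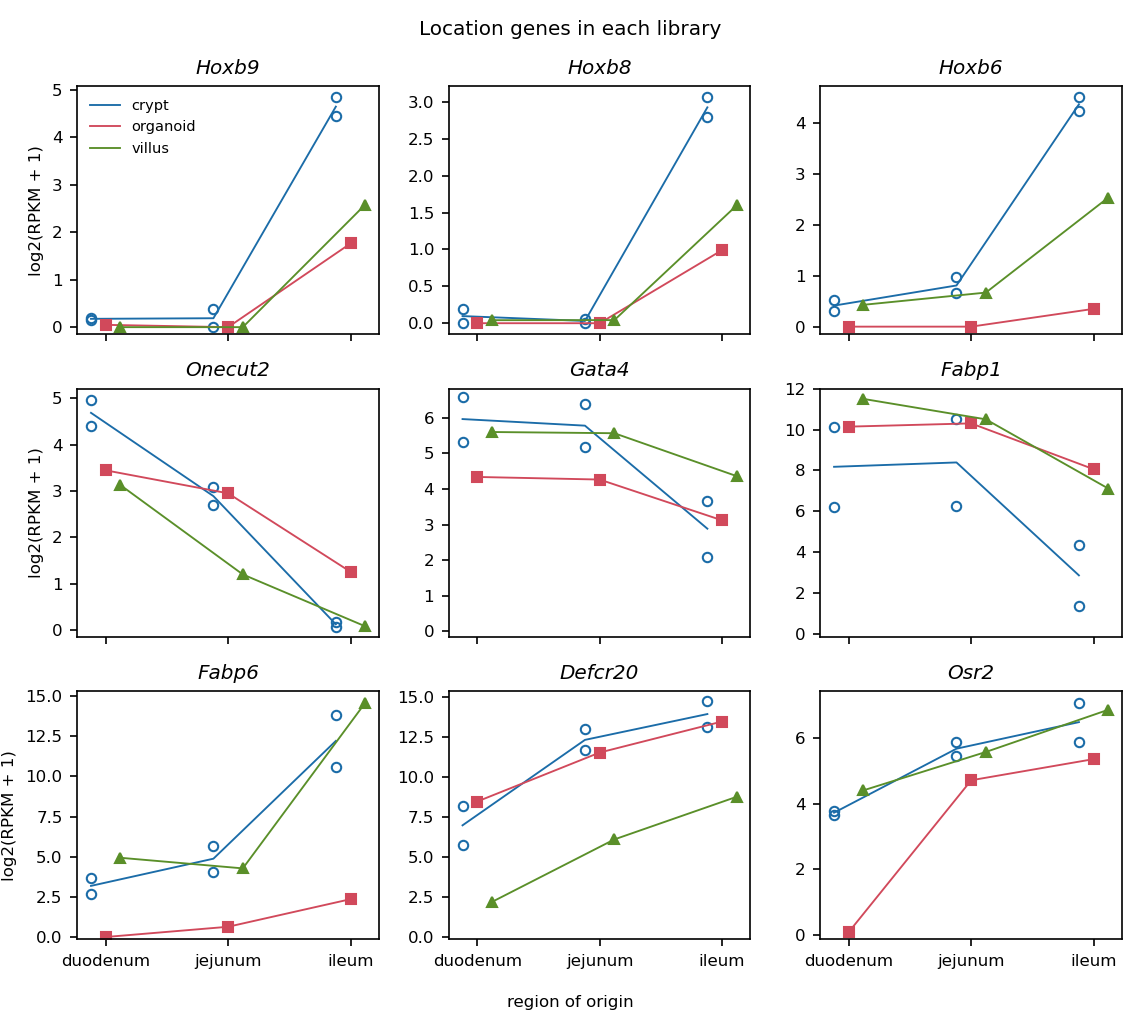
Log2(RPKM + 1) of 9 genes (y axis) in each library against origin (x axis), with open circles for crypts, filled squares for organoids, filled triangles for villi and lines joining the means. Hoxb9 is near 0 in duodenum and jejunum and high in ileum, at 24.2 RPKM in crypts, 2.39 in organoids and 4.98 in villi, and Onecut2 declines from duodenum to ileum in each tissue.

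Paneth, goblet and antimicrobial genes were higher in ileal crypts by camera at its preset correlation. None of these 3 list calls held with an estimated correlation. Among 12 Paneth cell genes the defensins Defcr20, Defcr21 and Defcr22 (now Defa20, Defa21 and Defa22) were higher in ileum by 6.96, 7.02 and 6.43, with adjusted p-values of 0.214, 0.119 and 0.152, and of 0.00476, 0.00297 and 0.00297 with the block. Adjusted over the list alone 3 Paneth cell genes were higher, and 11 with the block. Reads of these near-identical defensins cannot be assigned with certainty. No goblet cell gene of 8 passed adjusted over the list alone, and 7 did with the block, among them Spdef and Atoh1, factors of secretory cells, each higher by 1.17. Of 8 antimicrobial genes 5 were higher adjusted over the list alone, Reg3g, a lectin that kills bacteria, by 3.40 (adjusted p = 0.752, and 0.0286 with the block). The camera adjusted p-values were 5.27e-13, 8.22e-08 and 2.37e-05 for Paneth, goblet and antimicrobial genes, and 0.474, 0.411 and 0.474 with an estimated correlation. Paneth cell genes were lower in crypt replicate 2 than in replicate 1 at each origin.

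Bile acid genes as a list were higher in ileal than in duodenal crypts by camera at its preset correlation, and carbohydrate genes were lower. Neither call held with an estimated correlation. Of 9 bile acid genes 4 were higher and 1 lower in ileum adjusted over the list alone, and 6 and 1 with the block. Fabp6 (chromosome 11, 43409613 to 43415012) was higher by 9.03 (adjusted p = 0.103, and 0.0162 with the block), and Ostb (now Slc51b), which exports bile acids, by 3.19 (adjusted p = 1, and 0.0286 with the block). Slc10a2, the bile acid importer, and Fgf15, the hormone released on bile acid uptake, were higher by 3.19 and 2.84 and passed in neither fit, with blocked adjusted p-values of 0.303 and 0.218. Carbohydrate genes were lower in ileum by a median of -1.38, with 0 of 9 past the threshold adjusted over the list alone and 8 with the block. Fat absorption genes had a median of -0.31, with 9 of 21 higher in ileum. Genes of peptide digestion and amino acid transport went the way of the bile acid genes, with a median of 0.75, and were called by camera only with the block (adjusted p = 0.08, and 1.99e-05 with the block, where it was 0.436 with an estimated correlation). Fabp1 was lower by -5.32 and Apoa4 by -3.89, with adjusted p-values of 1 for both, and of 0.00687 and 0.00873 with the block. The camera adjusted p-values of the bile acid, carbohydrate and fat lists were 0.00119, 0.0012 and 0.0237, and 0.685, 0.708 and 0.834 with an estimated correlation. All 4 lists carry the replicate spread. Median log2 differences of replicate 2 from replicate 1 in duodenum, jejunum and ileum were 3.05, 2.76 and 2.23 for carbohydrate, 2.37, 2.16 and 1.95 for fat, 2.41, 2.35 and 3.21 for peptide and 0.26, 1.18 and 3.22 for bile acid genes. The ileal value of the bile acid genes, with 8 of 9 higher in replicate 2, exceeds their median of 2.51 between ileum and duodenum.

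Hormone genes and single genes of other functions also separated ileal from duodenal crypts. Among 17 enteroendocrine genes 2 were higher and 6 lower in ileum adjusted over the list alone, and Ghrl, the ghrelin gene, was lower by -2.90 (adjusted p = 0.21, and 0.0381 with the block). The list had a camera adjusted p of 0.000326, and 0.537 with an estimated correlation. The remaining duodenal genes with the block were the alcohol dehydrogenases Adh6a and Adh1, at -4.46 and -3.80, and the carboxylesterase 2210023G05Rik (now Ces2g), at -2.98, and Bex1 and Defcr4 were further ileal genes at 3.89 and 4.62. None passed without the block, where adjusted p-values were 0.676 for Adh6a, 0.603 for Adh1, 0.391 for 2210023G05Rik, 0.405 for Bex1 and 0.385 for Defcr4. The stem cell genes had a median of -0.07, and Lgr5 and Olfm4, which mark stem cells, did not pass in either fit. Neither did Lyz, the Paneth cell lysozyme, Cubn, the receptor of vitamin B12, the iron transporters Slc40a1 and Slc11a2, the digestive enzymes Lct, 2010204N08Rik (sucrase-isomaltase, now Sis) and Alpi, or Cyp3a11. The iron reductase Cybrd1 was too low to be tested in crypts.

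Between jejunal and duodenal crypts the clearest difference lay in the defensins. Defcr20, Defcr21 and Defcr22 were higher in jejunum by 5.34, 5.23 and 4.53. Without the block 0 genes passed in limma, while 126 had an unadjusted p under 0.05 and limma-voom on the recovered reads also gave 0. With the block the 3 genes that passed were these defensins, each with an adjusted p of 0.0252, and 467 genes had an unadjusted p under 0.05. Paneth cell genes had 3 members higher adjusted over the list alone and 8 with the block. Genes of peptide digestion and amino acid transport had 0 of 16 and 9 with the block, and MHC class II genes had 0 of 7 and 4 with the block. The camera adjusted p-values for these 3 lists were 3.92e-13, 0.000143 and 1.91e-05, and 0.695, 0.75 and 0.695 with an estimated correlation, so none of the 10 lists called held. Hox genes were called by camera (adjusted p = 0.0194) and lost with the block (0.0572) and with an estimated correlation (0.695), with a median of only 0.11. MHC class II genes were lower in jejunal crypt replicate 2 than in replicate 1 by a median of -2.83.

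Ileal and jejunal crypts differed in the same Hox genes. Hoxb9, Hoxb6 and Hoxb8 rose in ileum by 4.46, 3.56 and 2.90, with limma adjusted p-values of 0.0261, 0.0422 and 0.039, and were the 3 genes past the threshold, with 194 at an unadjusted p under 0.05. With the block 10 genes passed, 5 higher in ileum and 5 lower, and the larger ones were Hoxb5, Bex1, Fabp1, Apoa4 and Gata4. Fabp1 and Apoa4 were lower in ileum by -5.53 and -4.95, each with a blocked adjusted p of 0.0117. Leaving out 1 duodenal or jejunal crypt library left 0 genes. Without an ileal one Hoxb9 and Hoxb8 were no longer tested, Hoxb6 did not pass, and 1 other gene passed without ileum replicate 1. With the same genes tested Hoxb9 had 0.017 and 0.044 without ileum replicate 1 and 2, Hoxb8 0.025 and 0.0923, and Hoxb6 0.0575 and 0.171. The Hox list had 3 of 11 members risen, and 10 adjusted over the list alone, with a camera adjusted p of 3.15e-49 and 0.0233 with an estimated correlation (0.11 with the block as well). Lists lower in ileum were fat absorption (camera adjusted p = 6.14e-12, and 0.471 with an estimated correlation) and carbohydrate genes (4.86e-07, and 0.471), the latter with 0 of 9 members past the threshold adjusted over the list alone and 9 with the block. Goblet cell genes were higher (2.2e-09, and 0.319), with 0 and 7 members. Of 16 lists called, the Hox list alone held with an estimated correlation. Its tested members again include Hoxb9 and Hoxb8, which passed the filter only through the ileal libraries.

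Averaged over crypts, organoids and villi, ileum and duodenum differed in defensins, positional factors, bile acid genes and hormones. Defcr20 and Defcr21 rose in ileum by 6.38 and 5.99, Fabp6 by 7.52, and Osr2 by 3.32. Onecut2 fell, at -3.60, and so did the scavenger receptor Scarb1 and the carbonic anhydrase Car2, at -2.46 and -2.26. In all 72 genes passed of 11825, 49 higher in ileum and 23 lower, and 302 with the block, 220 higher and 82 lower. With limma-voom on the recovered reads 139 genes passed, 79 higher and 60 lower. The count was 38 without crypt ileum replicate 2, 39 without the ileal villi, 40 without the duodenal villi and 46 without crypt duodenum replicate 2. Limma adjusted p-values were 0.000571 for Defcr20, Defcr21, Onecut2 and Serpina1b, a protease inhibitor that rose by 3.65. They were 0.0103 for Fabp6 and Scarb1, 0.00704 for Osr2, 0.0386 for Tmigd1, an enterocyte membrane protein that rose by 4.68, and 0.0152 and 0.0227 for Ckb, a creatine kinase, and Car2. Leaving out 1 library lost some of these calls. Fabp6 had an adjusted p of 0.0569 without crypt duodenum replicate 2. Ckb had 0.0576 without that library, 0.0658 without the duodenal villi and 0.0635 without the ileal villi. Car2 had 0.0699 without crypt duodenum replicate 2, 0.0532 without crypt ileum replicate 2, 0.0716 without the duodenal organoids and 0.098 without the duodenal villi. Tmigd1 had 0.0817 and 0.0976 without crypt duodenum replicate 1 or 2, 0.0651 without crypt ileum replicate 2, 0.0552 and 0.0864 without the duodenal or jejunal organoids, and 0.177, 0.0587 and 0.153 without the duodenal, jejunal or ileal villi.

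Several lists moved with origin in this average. Of 11 Hox genes 5 rose, and 10 adjusted over the list alone, Hoxb9 by 3.31 and Hoxb7 by 2.52. Of 12 Paneth cell genes 3 rose, and 10 adjusted over the list alone (9 over all genes with the block). Of 3 proximal factors Onecut2 fell, and all 3, with Gata4 and Pdx1, adjusted over the list alone. Of 9 bile acid genes 3 rose, Fabp6, Fgf15 and the bile acid receptor Nr1h4 by 1.84, and of 9 antimicrobial genes 2, Reg3g by 2.97 and Duoxa2 by 2.29. Bile acid genes counted 6 higher and 1 lower adjusted over the list alone, and antimicrobial genes 5 and 1. The single calls of Fgf15, Nr1h4, Reg3g and Duoxa2 were lost without several of the libraries. Without crypt duodenum replicate 1 the adjusted p was 0.0711 for Nr1h4, 0.0585 for Reg3g and 0.0835 for Duoxa2, and without crypt duodenum replicate 2 it was 0.0773 for Fgf15, 0.0837 for Nr1h4 and 0.102 for Duoxa2. Without crypt ileum replicate 2 it was 0.088, 0.0813, 0.0506 and 0.108 for the 4 genes, and without crypt jejunum replicate 1 0.0527 for Nr1h4 and 0.0503 for Duoxa2. Without the duodenal organoids it was 0.0601 for Fgf15, 0.0534 for Nr1h4 and 0.0566 for Reg3g, without the jejunal organoids 0.0775, 0.0775, 0.0569 and 0.0733 for the 4 genes, and without the ileal organoids 0.052 for Fgf15. Without the duodenal villi it was 0.098, 0.15, 0.081 and 0.175, without the ileal villi 0.0983, 0.153, 0.0629 and 0.142, and without the jejunal villi 0.0598 for Nr1h4 and 0.0576 for Duoxa2. Slc10a2 was higher by 3.29 with an adjusted p of 0.0572, and of 0.0107 with the block. Among 18 enteroendocrine genes the hormones Ghrl and Gip fell, at -2.34 and -2.53, and Pyy and Nts rose by 3.66 and 2.90. Gip had an adjusted p of 0.0629 without the duodenal and 0.0614 without the ileal villi, and Pyy of 0.0576 without crypt duodenum replicate 2. Nts had 0.0699 without that library, 0.0672 without crypt ileum replicate 2, and 0.06 and 0.0569 without the duodenal or jejunal organoids. Camera called 17 lists, of which the proximal factors held with an estimated correlation (adjusted p = 0.014). The Hox, Paneth and antimicrobial lists had 0.0731, 0.118 and 0.0731, and the bile acid list 0.396.

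The question whether organoids keep the crypt difference was put to the genes called in crypts. All 4 kept their direction in organoids, where Onecut2 and Hoxb9 had a log2 ratio of ileum to duodenum of -2.19 and 1.71, and Hoxb8 and Hoxb6 of 0.99 and 0.35. All 4 also kept it in villi, at -3.05, 2.58, 1.56 and 2.11. A share of 4 in 4 has a Wilson interval of 51.0% to 100%. Of the 37 genes called with the block, 35 kept their direction in organoids (94.6%, interval 82.3% to 98.5%) and 25 had a ratio of at least 1 (67.6%). In random lists the second share had a median of 2.70% and reached 18.9% at most. In villi 36 of 37 kept their direction (97.3%, interval 86.2% to 99.5%) and 29 had a ratio of at least 1 (78.4%, against at most 29.7% in random lists). These organoid and villus ratios come from 1 library per origin and have no replicate check.

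Named genes kept in organoids came from several functions. Osr2 was listed at 0.054 RPKM in duodenal and at 40.1 RPKM in ileal organoids, a log2 ratio of 5.28. Defcr20, Defcr21 and Defcr22 had ratios of 5.01, 4.40 and 4.59, and Naaladl1, a brush border peptidase, of 4.37. On the duodenal side Dmbt1, a mucin-like scavenger protein, had -4.64, Adh1 -3.23, Slc1a3, a glutamate transporter, -2.15 and Fabp1 -2.08. Fgf15 had 2.99, at 2.76 RPKM in duodenal and 28.9 in ileal organoids. Fabp6 was at 4.12 RPKM in ileal organoids and listed at 0 in duodenal ones, against 24600 RPKM in ileal villi. Genes with a small ratio in organoids were Mep1a, a brush border peptidase, at 0.23, Dfna5h (now Gsdme) at 0.46, Hoxb4 at 0.47 and Tceal8 at -0.41, against crypt differences of 3.34, 3.18, 2.84 and 2.72. In villi, Mep1a and Dfna5h had ratios of 3.46 and 3.30.

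**Figure D2:**
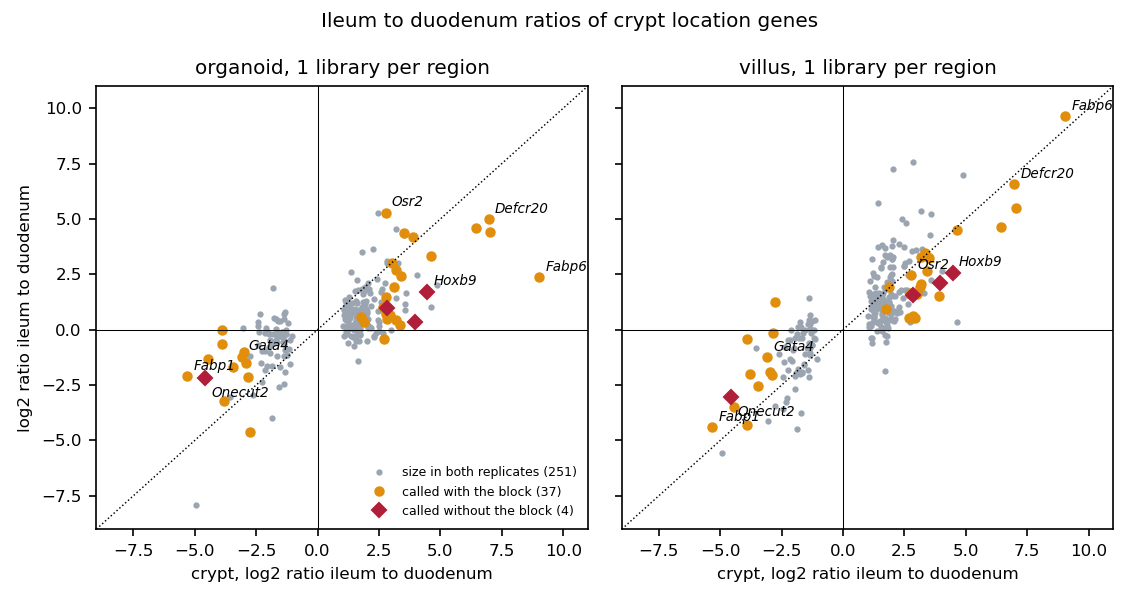
Log2 ratio of ileum to duodenum in crypts (x axis) against the ratio in organoids (left, y axis) and villi (right, y axis), one point per gene and y = x dotted. Red diamonds are the 4 genes called in crypts, orange points the 37 called with the replicate block and grey points the 251 with a ratio of at least 1 in both crypt replicates, of which 209 have the crypt direction in organoids and 228 in villi.

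A list by size, chosen after seeing the data, had smaller shares of kept genes. It holds 251 genes with a log2 ratio of at least 1 in the same direction in both crypt replicates, 174 higher in ileum and 77 lower. In organoids 209 kept their direction (83.3%, Wilson interval 78.2% to 87.4%) and 91 had a ratio of at least 1 (36.3%, against at most 6.37% in random lists). In villi the numbers were 228 (90.8%, interval 86.6% to 93.8%) and 154 (61.4%, against at most 15.9%). For jejunum against duodenum 66 of 82 such genes kept their direction in organoids (80.5%), and for ileum against jejunum 109 of 127 (85.8%). Across all 11123 genes, which are not independent replicates, the crypt ratio of ileum to duodenum had a Pearson correlation of 0.353 with the organoid ratio and of 0.46 with the villus ratio (Spearman 0.153 and 0.227). Median ratios of the bile acid genes were 2.51 in crypts, 1.43 in organoids and 2.52 in villi, those of the Paneth cell genes 1.93, 1.08 and 2.85, and those of the goblet cell genes 1.41, 0.13 and 1.53. Carbohydrate genes had -1.38 in crypts, 0.16 in organoids and -0.62 in villi. The 2 villus libraries also differed in other cell types. Median villus ratios were 1.32 for smooth muscle, 1.45 for red cell, 0.73 for proliferation and 0.51 for stem cell genes, and -0.51 for lymphocyte and -0.70 for interferon genes, so these ratios do not separate origin from the make-up of the 2 samples.

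Whether the ileum-duodenum difference itself differed from crypts was tested for each gene. Over all 12740 genes limma called 0 for organoids and 0 for villi, with 333 and 463 at an unadjusted p under 0.05, and limma-voom also gave 0 and 0. Adjusted over the 4 crypt genes alone, Hoxb9, Hoxb8, Hoxb6 and Onecut2 all differed, each with a smaller difference in organoids and in villi than in crypts. Over the 37 genes called with the block, 26 differed in organoids, 24 of them with a smaller difference, and 13 differed in villi, all with a smaller one. The same crypt libraries chose these genes, which favours large crypt differences.

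Villi differed from crypts in the genes of absorption, defence and cell division. The purine enzyme Ada, the lipid enzyme Enpp7, Apoa4, the membrane protein Pmp22 and 2010109I03Rik (now Ly6m) rose in villi, and Lyz, Ang4, Defcr26 and AY761184 (now Defa39), all secreted by Paneth cells, fell together with the immediate early gene Fosb. Ada rose by 6.34 (SE 0.58, limma adjusted p = 5.58e-06), Enpp7 by 6.28 (1.78e-05), Apoa4 by 6.21 (0.000479), Pmp22 by 6.02 (0.000528) and 2010109I03Rik by 6.96 (1.43e-05). Log2 fold changes of the lower genes were -5.96 for Fosb (SE 0.29, 1.44e-07), -5.77 for Lyz (1.26e-05), -5.71 for Ang4 (3.99e-06), -5.57 for Defcr26 (2.39e-06) and -5.56 for AY761184 (8.31e-06). In all 6247 of 11825 genes passed, 2402 higher in villi and 3845 lower. The origins served as the replicates of villi, so these calls do not separate tissue from a preparation shared by the villus libraries. The median of all genes was -0.19, and 0.02 with median-ratio scaling, where 6672 genes passed, 3661 higher and 3011 lower.

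Absorptive functions rose in villi. All 21 fat absorption genes rose, with Npc1l1, which takes up cholesterol, at 4.14, Abcg8 at 3.01 and Cd36 at 2.81. Of 16 genes of peptide digestion and amino acid transport 15 rose and 1 fell, Slc6a19 rising by 4.61. Of 17 enterocyte genes 15 rose, among them Nt5e by 4.33, Lct by 5.04 and Alpi by 3.77. Xenobiotic genes rose in 13 of 21 cases, Cyp3a13 by 3.79 and Cyp3a11 by 4.75, carbohydrate genes in 6 of 9, G6pc by 4.26, and bile acid genes in 5 of 9, Ostb by 2.06 and Fgf15 by 2.42. Iron genes rose in 5 of 10 cases, Slc11a2 by 1.01, and Tfrc fell, at -2.95. Cubn rose by 3.37. Leaving out 1 library lost 3 of these calls. Slc11a2 had an adjusted p of 0.125 without the ileal villi, and Fgf15 of 0.183 without the ileal and 0.0716 without the jejunal villi. Ostb had 0.0548, 0.0647 and 0.055 without crypt replicate 1 of duodenum, jejunum or ileum, and 0.181 and 0.0869 without the duodenal or ileal villi. Crypt genes went the other way. All 16 proliferation genes and all 12 Paneth cell genes fell, with Top2a at -3.73 and Mcm3 at -3.36, and 14 of 15 stem cell genes fell, with Ascl2 at -3.61, Sox9 at -3.19, Olfm4 at -4.79 and Lgr5 at -2.40. Of 13 immediate early and heat shock genes 11 fell, with Egr1 at -4.85.

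Villi also held RNA of cells outside the epithelium. All 9 lymphocyte genes rose, Cd3e, a T cell receptor chain, by 3.45 and Gzma by 4.91, all 6 smooth muscle genes rose, Acta2 by 3.79 and Actg2 by 3.23, and 6 of 9 myeloid genes rose, C1qa by 3.32, while 2 fell. Red cell genes rose in 3 of 4 cases and fibroblast genes in 3 of 4. Of epithelial tuft cell genes 6 of 7 rose. MHC class II genes rose in 6 of 7 cases, H2-Ab1 by 3.40, and interferon genes in 11 of 14, Ifit1 by 3.13 and Isg15 by 3.60. Camera called 20 of 31 lists, the fat, lymphocyte, proliferation, interferon, Paneth, smooth muscle and stem cell lists with adjusted p-values of 4.06e-09, 5.62e-09, 8.34e-08, 1.29e-06, 1.42e-06, 3.23e-06 and 1.91e-05. With an estimated correlation these 7 had adjusted p-values of 0.33 to 0.356, and none of the 20 held. The self-contained test fry called 20 lists, 19 of them also called by camera. Hox genes were not called (adjusted p = 0.138), and 0 of 11 passed adjusted over the list alone. Over all genes Hoxa3, Hoxb4, Hoxb5 and Hoxb7 were lower in villi, and none of the 4 passed without the ileal villi (0.259, 0.121, 0.351 and 0.174).

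Organoids differed from crypts by higher detoxification and hormone genes and lower early response genes by camera at its preset correlation. None of these list calls held with an estimated correlation. Mt2, a metallothionein, S100g, an intestinal calcium-binding protein, Gsta3, a glutathione transferase, and the cytochromes Cyp2c66 and Cyp2c29 rose, and Fabp6, the carbonic anhydrase Car4, and the regulators Purb, Usp2 and Atf3 fell. Mt2 rose by 6.21 (SE 0.79, limma adjusted p = 7.05e-05), S100g by 6.06 (3.22e-05), Gsta3 by 5.54 (1.04e-06), Cyp2c66 by 5.34 (1.04e-05) and Cyp2c29 by 5.24 (2.41e-06). Log2 fold changes of the lower genes were -5.76 for Fabp6 (0.00136), -4.96 for Car4 (0.000196), -4.89 for Purb (2.11e-05), -4.56 for Usp2 (1.04e-06) and -4.39 for Atf3 (5.62e-06). In all 5603 genes passed, 2760 higher in organoids and 2843 lower, and 3467 without the ileal organoids. As for villi, these calls do not separate tissue from a preparation shared by the organoid libraries. Without the 20 most abundant genes, which moves the median of all genes from 0.00 to -0.14, 2263 were higher and 3496 lower.

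The groups that changed in organoids were few. Of 13 immediate early and heat shock genes 11 fell, with Dusp1 at -2.95 and Junb at -2.05. Of 18 enteroendocrine genes 10 rose, Tph1, which makes serotonin, by 2.65, Gcg by 4.00 and Tac1 by 3.89. Xenobiotic genes rose in 13 of 21 cases and fell in 1, epithelial transcription factors fell in 13 of 17 cases, with Elf3 at -2.20, Klf4 at -2.40 and Hnf4a at -1.89, and rose in 1. Of 5 genes of fetal-like epithelium 4 rose, Il1rn by 3.92 and Ly6a by 4.59. The camera adjusted p-values of these 5 lists were 3.32e-05, 0.000413, 0.000751, 0.00283 and 0.00847, and with an estimated correlation 0.966 to 0.976. Fry did not call the xenobiotic list (adjusted p = 0.0758, and 0.000351 with the block). In this comparison the block made 1370 false calls of genes on simulated data. Results that only the block gives are therefore not safe, here and in the next paragraph.

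Stem and Paneth cell genes as groups were not called between organoids and crypts. Stem cell genes rose in 3 and fell in 3 of 15 cases, Lgr5 rising by 1.98 and Prom1 by 1.43, and Olfm4 did not pass (adjusted p = 0.332). Paneth cell genes rose in 2 of 12 cases (3 rose and 1 fell with the block), Mmp7 by 1.23, and Lyz did not pass (adjusted p = 0.695). The call of Mmp7 was lost without crypt replicate 2 of duodenum (0.0623), jejunum (0.0686) or ileum (0.0685), and without the duodenal (0.147), jejunal (0.0808) or ileal (0.11) organoids. Proliferation genes rose in 1 and fell in 5 of 16 cases. Of 11 Hox genes 7 fell, and 8 adjusted over the list alone, with Hoxb6 at -1.75 and Hoxb4 at -1.67 and a camera adjusted p of 0.154. Without the ileal organoids the adjusted p was 0.108 for Hoxb6 and 0.085 for Hoxb4. Single digestive and antimicrobial genes went both ways. Sucrase-isomaltase (2010204N08Rik), Fabp1, Reg3g and Pap (now Reg3b) rose by 4.05, 3.03, 4.24 and 4.70, while Lct, the fatty acid transporter Slc27a4, Cubn and Ostb fell, at -2.92, -3.53, -2.01 and -2.66. Fabp1 had an adjusted p of 0.0511 and 0.0572 without crypt replicate 1 of duodenum or jejunum, and of 0.0643 and 0.212 without the jejunal or ileal organoids. Lct had 0.0859 and 0.0996 without the duodenal or jejunal organoids, and Ostb 0.0581 without the ileal ones. Cubn had 0.063 and 0.0614 without crypt replicate 2 of duodenum or jejunum, and 0.135 and 0.179 without the jejunal or ileal organoids. Cybrd1 rose by 1.20. Cyp3a11 and Alpi, at 2.21 and -1.38, did not pass (adjusted p = 0.119 and 0.291, and 0.000257 and 0.00664 with the block). The blocked calls of both are not safe. MHC class II genes fell in 4 of 7 cases, with H2-Ab1 at -3.63 and Cd74 at -3.99, and the list was higher in crypt replicate 1 than in replicate 2. The list was called by camera only with the block (adjusted p = 0.166, and 0.0291 with the block, where it was 0.967 with an estimated correlation). Cd74 had an adjusted p of 0.0591 and 0.0572 without the jejunal or ileal organoids.

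Organoids were higher than villi in Paneth cell, proliferation and stem cell genes and lower in genes of absorption and of lymphocytes. Ang4 and Mmp7 of Paneth cells, the secretory pathway gene Tmed6, Mt2 and 1190003M12Rik (now Gkn3) were higher in organoids, and Enpp7, Pmp22, Lct, 2010109I03Rik and H2-Ab1 were lower. Of these, Mt2 was also higher in organoids than in crypts, and Lct and H2-Ab1 were also lower, so organoids were not at the crypt level for them. Mt2 was higher by 6.81 (SE 0.91, limma adjusted p = 4.17e-05), 1190003M12Rik by 6.79 (4.04e-06), Ang4 by 6.71 (2.17e-06), Tmed6 by 6.46 (1.66e-06) and Mmp7 by 6.34 (1.96e-06). Log2 fold changes of the lower genes were -8.94 for Enpp7 (3.44e-06), -8.86 for Pmp22 (5.62e-05), -7.96 for Lct (2.67e-05), -7.70 for 2010109I03Rik (1.26e-05) and -7.03 for H2-Ab1 (8.34e-06). In all 7282 genes passed, 4257 higher in organoids and 3025 lower. Neither tissue has replicates within an origin, so a preparation shared by the libraries of a tissue is not separated from the tissue here either. The median of all genes was 0.21, and -0.00 with median-ratio scaling, where 3695 were higher and 3860 lower. Of 12 Paneth cell genes 11 were higher, of 16 proliferation genes 15 and of 15 stem cell genes 12, Lgr5 by 4.38. Of 21 fat absorption genes 16 were lower, of 16 peptide genes 13, of 14 interferon genes 13, and all 9 lymphocyte, 6 smooth muscle and 7 MHC class II genes. Camera called 15 lists, with adjusted p-values of 2.69e-06 for lymphocyte, 1.19e-05 for fat and 3.82e-05 for Paneth cell genes, and 0.53, 0.553 and 0.53 with an estimated correlation. None of the 15 held with it. The bile acid list, with 4 of 9 lower, was called (0.0451) and lost with median-ratio scaling (0.0716).

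**Figure D3:**
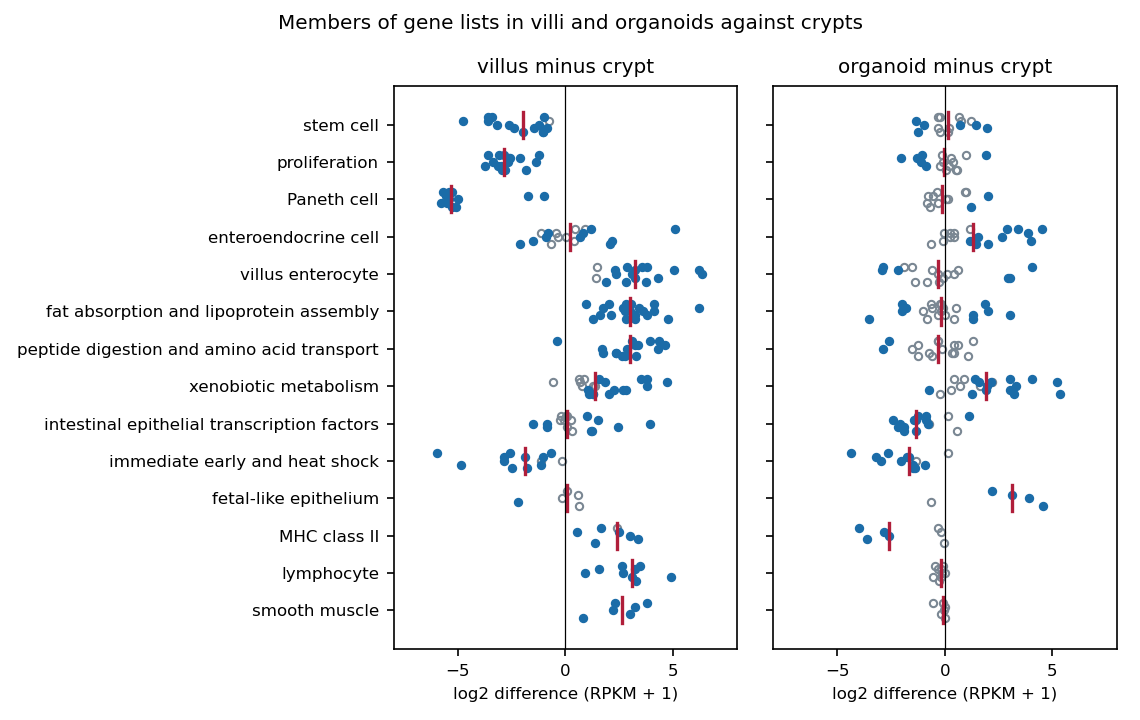
Log2 difference of each member of 14 gene lists (one dot per gene, log2(RPKM + 1) scale), villus minus crypt and organoid minus crypt, with filled dots for an adjusted p under 0.05 and a red bar at the median. In villi the 12 Paneth cell genes lie below 0 with a median of -5.34 and the 21 fat absorption genes above 0 with a median of 3.01.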

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

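All tests in this part other than the difference between tissues itself were chosen after the results had been seen, and so was the restriction to genes called with the replicate block. The groups hold at most 2 libraries, too few to set a sample against the others of its group. The MHC class II test was made with 2 versions of the marker set, which gave the same result, and the version with all markers is given.

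On the log2(RPKM + 1) scale the Hox genes and Onecut2 separate ileal from duodenal crypts more widely than ileal from duodenal organoids or villi. The test of that difference, adjusted over these 4 genes alone, passed for each. On this scale a gene near 0 at 1 origin has a difference set by its level at the other. Hoxb9, near 0 in duodenum, had a lower ileal level in organoids and villi than in crypts. Its smaller difference therefore does not show a weaker relative contrast. The organoid difference minus the crypt difference was -2.75 for Hoxb9, -1.84 for Hoxb8, -3.61 for Hoxb6 and 2.38 for Onecut2 (limma adjusted p = 0.00108, 0.00108, 0.000672 and 0.00835). The villus difference minus the crypt difference was -1.89, -1.27, -1.85 and 1.52 (adjusted p = 0.00653 for the 3 Hox genes and 0.0464 for Onecut2). Tested with the block over the same 4 genes, Onecut2 had an adjusted p of 0.0484 in villi, close to the threshold, and over the 37 genes called with the block it did not pass there (adjusted p = 0.0895). Among the genes called with the block, 26 differed from crypts in organoids and 13 in villi, adjusted over those 37 genes. None of these genes passed over all genes tested. They were selected for a large difference in the same crypt libraries, and the single organoid and villus libraries are assumed to vary like crypts.

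Tceal8 and Dmbt1 went against the crypt direction in 1 tissue each. Tceal8 was higher in ileal crypts and had a log2 ratio of -0.41 in organoids, a change of -3.12 against crypts (adjusted p = 0.0115 over the list alone). Dmbt1 was higher in duodenal crypts and organoids and had a ratio of 1.25 in villi, a change of 4.02 (adjusted p = 0.0122 over the list alone). No explanation was tested for either gene.

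The first pattern weighed is the loss of origin differences in organoids, where 91 of the 251 genes chosen by size kept a log2 ratio of at least 1, against 154 in villi. The gap between the tissues lay more on the ileal side, where 35.1% of 174 genes were kept in organoids and 66.7% in villi, than on the duodenal side, with 39.0% and 49.4% of 77. Random lists matched to the ileal genes were kept in a median of 2.87% in organoids and 10.9% in villi, and had the ileal direction in 52.3% and 72.4% of cases, so part of the ileal share in villi is also seen in random genes. Too few organoid reads would leave well covered genes kept as often as in villi. Among 98 genes with at least 1000 organoid reads, 42.9% were kept in organoids and 67.3% in villi, a difference of 24.5 points (95% interval 12.1 to 36.8, genes treated as independent), which argues against depth as the whole cause. If the lost genes were those of villus epithelium, genes higher in villi would be kept less often. They were kept in 41.8% of cases and genes lower in villi in 40.0%, so they were kept less often by -1.77 points (interval -17.3 to 13.8), too wide to tell. Of the 97 genes called in neither direction between villi and crypts, 28.9% were kept in organoids and 67.0% in villi. A change in culture and the selection of genes on crypt values stay open, untested.

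The second pattern is the enterocyte RNA in crypt replicate 2. Whole villi in the preparation would bring lymphocyte RNA with it. For each marker the rise from replicate 1 to replicate 2 was taken as a percentage of the gap between replicate 1 and villi. Markers needed at least 10 RPKM in villi and a 4-fold excess there over replicate 1. This left 6, 4 and 2 lymphocyte markers in duodenum, jejunum and ileum. Their median rise was at most 4.19% of the gap, while that of the enterocyte markers was at least 28.8%. Single markers spread widely, enterocyte ones from -0.13% to 232% in duodenum, 2.49% to 101% in jejunum and 1.19% to 57.8% in ileum, and lymphocyte ones up to 1.11%, 7.98% and 4.94%. Of 17 enterocyte markers 15, 15 and 13 lay above the highest lymphocyte marker, and Ada and Nt5e lay at the lymphocyte level at each origin. Whole villi as the whole source are therefore argued against, and a share of a few percent stays open. A different share of reads in exons does not account for it either, since a log2 difference of at least 2.55 remained after scaling to gene reads. Detached villus epithelium without the core and crypts sampled further up were not tested as sources. The lymphocyte markers were not divided into those of the villus core and those of the epithelium. Their low share therefore does not set detached epithelium apart from whole villi.

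The third pattern is the MHC class II RNA in crypt replicate 1, which reached a median of 109% of the villus level in jejunum and 27.9% in ileum. Immune cells would bring their other transcripts, but lymphocyte and myeloid markers reached a median of at most 3.83% there. All 8 lymphocyte and 5 of 6 myeloid markers lay below the lowest MHC class II gene at both origins. The exception was Lyzs (now Lyz2), at 594% and 659%, whose reads cannot be assigned with certainty against those of the Paneth cell lysozyme Lyz, and the highest of the other myeloid markers had 5.61% and 6.71%. Immune cells that carry these markers are therefore an unlikely sole source there. Many of the lymphocyte markers are T cell and cytotoxic genes, which bear less on MHC class II than the myeloid markers. The lists hold no markers of dendritic cells, so those cells stay open and were not tested. In duodenum the higher of those medians was 24.0%, above the 17.4% of the MHC class II genes, so immune cells and epithelial expression cannot be told apart there because both lie in the same range. Expression by the epithelium itself stays open and was not tested.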

How the results depend on the processing

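Median-ratio scaling, limma-voom on the recovered reads, another transcript per symbol, the block combined with either of the first 2, the block for differences between tissues and for villus or organoid against crypt, leaving out all crypt libraries of 1 number, and testing the same genes when 1 crypt library is left out were chosen after seeing the data. The planned count-based tests and their scalings were not run because the values are RPKM. Of 9214 alternatives to the 406 calls of named genes, 8658 kept the call, 556 lost it and 0 reversed its direction. Most of these calls are from tissue comparisons. The 4 calls between ileal and duodenal crypts were all lost with no filter on low values and with limma-voom without the block. A pseudocount of 0.1 lost 3 of the 4. All 4 were kept with the block, a filter at 1 CPM, another transcript per symbol and without the 20 most abundant genes. The cause was not tested unless stated.

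The replicate numbers pair the crypt libraries, and the block moved the crypt counts most. It raised ileum against duodenum from 4 to 37 genes, and to 75 with median-ratio scaling and 150 with limma-voom. Jejunum against duodenum went from 0 to 3, 3 and 5, and ileum against jejunum from 3 to 10, 19 and 32. Across tissues it raised ileum against duodenum from 72 to 302. Organoid against villus went from 7282 to 7943. The planned form of the block, with villi and organoids in a level of their own, is confounded with tissue for villus or organoid against crypt. With the replicate difference centred within crypts instead, villus against crypt went from 6247 to 7039 and organoid against crypt from 5603 to 6594. That form takes the spread between replicates out of the error although the crypt mean still carries it, and on simulated data, with the effect in crypt replicate 2 alone, it made 1429 and 1370 false calls, against 0 and 1 without the block. Calls that only this form makes are therefore not safe. It left both differences between tissues at 0. It lost no call of a named gene, and further named genes gained one. Among lists it lost 3 calls by camera for jejunum against duodenum, Hox, enteroendocrine, and gastric and Brunner gland genes (adjusted p = 0.0572, 0.0572 and 0.0562 with the block, and 0.0194, 0.0225 and 0.0194 without). It added bile acid (0.0138) and xenobiotic genes (0.0314) there. It added peptide genes for ileum against duodenum in crypts (1.99e-05) and across tissues (9.62e-06) and for ileum against jejunum (0.00645), and xenobiotic (0.00518), MHC class II (0.0162) and immediate early genes (0.0187) for ileum against duodenum in crypts. For organoid against crypt it added MHC class II genes (0.0291). It changed no other call of a list.

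Other settings moved the small crypt counts. A pseudocount of 0.1 gave 1 gene for ileum against duodenum and 0 for ileum against jejunum. That gene was Onecut2, so the 3 Hox calls were lost. Median-ratio scaling kept the 3 Hox genes for ileum against duodenum and lost Onecut2. No filter on low values gave 0 and 0, and limma-voom without the block gave 0 and 0. For ileum against jejunum 2 genes passed with a filter at 1 CPM and 2 without the 20 most abundant genes. Across tissues, ileum against duodenum gave 113 with a pseudocount of 0.1, 17 with no filter, 139 with limma-voom, 25 in only the libraries of the groups compared, where fewer samples enter, 113 without the 3 crypt replicate 2 libraries and 155 without the 3 replicate 1 libraries. With no filter the differences between tissues gave 362 genes for organoids and 497 for villi. Of these, 298 and 396 are at 0 in all 6 crypt libraries, so their spread is estimated from values without any, and 301 and 388 are removed by the filter.

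Leaving out 1 library gave 0 to 1 genes for ileum against duodenum in crypts, 0 to 0 for jejunum against duodenum, 0 to 1 for ileum against jejunum and 38 to 94 across tissues. With the same genes tested the 3 crypt ranges were 0 to 6, 0 to 0 and 0 to 4, and Hoxb9 then passed in both ileum comparisons without either ileal library. It gave 4491 to 6663 for villus against crypt, 3467 to 6379 for organoid against crypt and 6139 to 7771 for organoid against villus. The differences between tissues stayed at 0, and leaving out an ileal or duodenal organoid or villus library gives no value for its own difference. A single library left in a group is assumed to vary like the others. Without the 3 crypt replicate 2 libraries villus against crypt had 7198 genes, and without the 3 replicate 1 libraries 5606.

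List tests depended on the correlation assumed. Of 96 calls by camera over all comparisons, 3 held with an estimated correlation. Fry, counted on its own, called 53 lists. By comparison, the estimated correlation and fry gave 1 and 1 of 13 for crypt ileum against duodenum, 0 and 0 of 10 for jejunum against duodenum, 1 and 1 of 16 for ileum against jejunum, and 1 and 6 of 17 across tissues. The estimated correlation gave 0 for villus against crypt, organoid against crypt and organoid against villus, where fry gave 20, 5 and 20, of which camera also called 19, 4 and 15. Median-ratio scaling also gave 96 calls, but not all the same ones. It kept 8 of 10 for jejunum against duodenum, 19 of 20 for villus against crypt and 14 of 15 for organoid against villus. In the other comparisons it kept every call.

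The share of crypt genes that keep their direction rests on 4 genes, and random lists of 4 genes also reach 100%, so it says little about stability. It was 100% in organoids and villi under pseudocounts of 0.1, 0.5 and 5, a log2 fold change of at least 1, an average log2 CPM of at least 3, median-ratio scaling and without crypt ileum replicate 1, where 1 gene is left. Other crypt lists of 1 library fewer hold no gene and give no value. With the block it was 94.6% and 97.3%, and for the list by size 83.3% and 90.8%. Depth limits the low genes, since 1 read in a 2-kb gene is worth up to 0.0949 RPKM, so a listed 0 for a Hox gene in organoids does not show that it is silent.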

Other observations

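The counts over other splits of the libraries were made after the results had been seen.

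Cholesterol synthesis and retinoid genes were called by camera in several comparisons. In ileal against duodenal crypts the 16 cholesterol genes had a median log2 fold change of 0.39 (camera adjusted p = 0.0106, and 0.834 with an estimated correlation), and the 8 retinoid genes had -0.90 (0.0081, and 0.708). Among the retinoid genes, Rbp2, a retinol-binding protein, was lower in ileal crypts, at -3.46 (limma adjusted p = 1, and 0.00907 with the replicate block). Across tissues the cholesterol genes had a median of 0.76 (0.000135, and 0.557), with no member past the threshold adjusted over the list alone and 2 with the block. That average covers tissues that differ. The median log2 ratio of ileum to duodenum over the 17 cholesterol genes was 0.39 in crypts, -0.29 in organoids, where 5 were higher in ileum, and 2.24 in villi, where all 17 were higher and 15 had a ratio of at least 1. The organoid and villus ratios come from 1 library per origin and have no replicate check. In the same 2 villus libraries smooth muscle, red cell, proliferation and Paneth cell genes were also higher in ileum, by medians of 1.32, 1.45, 0.73 and 2.85, and lymphocyte and interferon genes lower, at -0.51 and -0.70, so the cholesterol ratio in villi does not separate origin from the make-up of the 2 samples. Of 4 gastric and Brunner gland genes Pgc, a pepsinogen, was lower in ileum across tissues, at -2.32 (limma adjusted p = 0.00189). The pancreatic protease Ctrb1 rose in organoids against crypts by 3.38 (limma adjusted p = 1.54e-05), at 18.0, 23.0 and 7.04 RPKM in the 3 organoid libraries.

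Reg1, a secreted lectin of regenerating epithelium, was lower in ileum than in duodenum across tissues, at -5.84 (limma adjusted p = 0.00704). It was at 879, 52.3 and 17.4 RPKM in villi of duodenum, jejunum and ileum. The gene was chosen after its values were seen.

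Other splits of the same libraries into groups of equal size were fitted for each comparison with at least 3 libraries per group. For villus against crypt 1 of 84 splits, the real one, gave as many as 6247 genes, and the highest of the others gave 1577. For organoid against crypt it was 1 of 84, with 5603 genes and 598 for the highest other. For ileum against duodenum across tissues it was 1 of 35, with 72 genes and 0 for the highest other, and 1 of 35 with the replicate block, with 302 and 0. These divisions take any libraries. Among the 27 splits for villus or organoid against crypt that take 1 library per origin, only the real one was as large. The highest others were 1577 and 598. Those highest splits set the crypt libraries of replicate 1 against the rest, so they follow the replicate number. Every other split mixes the tissues within a group, so the tissue difference widens the spread and keeps the count low. Paired crypt libraries are also not freely exchangeable. These counts therefore do not exclude chance, or a preparation shared by the libraries of a tissue. For ileum against duodenum the other splits mix the origins in the same way, and most of them ignore tissue. Just 12 splits keep the tissues balanced, too few for a share under 0.05, with 0 genes for the highest other. Organoid against villus has only 10 splits, too few for a share under 0.05, with 7282 genes for the real one, 1 of the 10, and 0 for the highest other.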
